A study of Homo sapiens with 9 samples.

How the data were processed

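RNA-seq was measured in 9 libraries of the THP-1 cell line, 3 from solvent-treated cells, 3 from cells with lupeol at 50 µmol/L and 3 at 80 µmol/L, taken after 48 h per the labels' protocols. One treatment label of the lower dose lacks the micro prefix of its unit, and that library was taken as 50 µmol/L from its sample description and the other labels of its group. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

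The authors deposited 1 table of raw counts per gene for all libraries, with exon coordinates and a gene length in bases. The count columns hold whole numbers whose totals run from 26134744 to 38430299. Intervals and spreads cover these libraries only, since reads without molecular identifiers are not independent molecules. Per the submitters' processing notes, the tool was Bowtie 0.12.2 and the genome build was the mouse build mm8. The deposited table itself holds human Ensembl genes: 35993 of its versioned gene IDs are in GENCODE release 29, and all 35993 have the same chromosome, start and end there, which is on GRCh38. The build in the notes and the table therefore conflict, and coordinates were used only for names. The counting tool, its use of strand and its treatment of reads with several alignments are not given in the sources used here. Antisense genes and genes with near-identical copies are therefore reported as uncertain.

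The table holds 67928 genes, 1 of which (ANK2) has empty values and was left out. A count in at least 1 library was found for 33754 genes, of which 33683 took their symbol from a table of gene names, 65 from GENCODE and 6 had none. There are 6395 genes on alternate or patch scaffolds. All mitochondrially encoded genes stand at 0 in every library, so the list of 13 such genes could not be tested. Of the control columns, 2 carry one shared heading, so each was taken as a control library without a number of its own, named A and B. They differ from each other by more than sampling noise (chi-square per degree of freedom 28.0). Every per-sample column was used.

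Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (17568 genes), scaled by TMM and tested by the quasi-likelihood F test with robust dispersion, in 1 fit of all 9 libraries with a term per group. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p under 0.05. The common biological coefficient of variation was 0.178, with 6 residual degrees of freedom and a median of 12 prior degrees of freedom. The contrasts were lupeol 50 against control, lupeol 80 against control, lupeol 80 against lupeol 50, and a test of any difference among the 3 groups. Levels are TMM-scaled CPM, computed here, given as mean ± SD over 3 libraries, and fold changes are log2 values ± SE. This SE was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Designs, gene lists, the naming rule and most alternatives were fixed before the data were examined.

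For 35 gene lists with 757 members, camera of limma 3.58.1 was run on log2 CPM (prior count 2) with a preset correlation of 0.01, over the 31 lists with at least 5 tested members, adjusted over lists within a contrast. The same lists were tested with an estimated correlation and with fry. No list was called in any contrast with an estimated correlation, where the smallest adjusted p was 0.59, 0.68 and 0.83 in the order of the contrasts above, and 16 of the lists had an estimated correlation over 0.2. Calls of single members are also given adjusted over the list alone. This adjustment does not cover the number of lists. Over all genes, edgeR gave an unadjusted p under 0.05 for 12.4%, 19.5% and 15.4% in the order of those contrasts. A count of such members therefore does not by itself set a list apart from other genes. The lists cover sterol, fatty acid and LXR genes, PPAR targets, stress responses (ATF4, ER, NRF2, heat shock, metallothionein, p53), DNA replication, mitosis, apoptosis, NF-kB, interferon, antigen presentation, monocyte, granulocyte, HOXA and retinoic acid programmes, MYC targets, ribosomal proteins, respiratory chain and mitochondrially encoded genes, glycolysis, lysosome, iron, immediate-early, aryl hydrocarbon receptor and histone genes, and markers of 5 other cell types.

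Named genes follow a rule. For each dose against control, these are the 10 called genes with the largest rise and the 10 with the largest fall among those with a symbol, a mean of at least 5 CPM, and the 3 treated libraries all on one side of the controls. For lupeol 80 against lupeol 50 the same applies with 5 and 5, and up to 4 called members per list are added. Where fewer than 5 genes were called, the 5 with the smallest p are named as not called. A list with no called member may show its 2 members of highest mean as values. Further genes were chosen after their values were seen and are marked so. XIST and Y-linked genes were left out, and results for some genes that the rule or the later choice names are not reported.

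The steps were tested on simulated counts with 200 changed genes. For lupeol 50 against control (17104 genes), 59 of 100 genes changed 2-fold and 29 of 100 changed 1.5-fold were recovered, with 7 false calls. For lupeol 80 against control (17095 genes) these were 55, 22 and 12, and for lupeol 80 against lupeol 50 (17116 genes) 62, 16 and 9. The list test called the 1 simulated list and 0 others in each contrast. Genes were drawn independently in these counts, so this does not show how often the list test calls unchanged lists with correlated members. In counts simulated with GC trends but no changed genes (17107 genes), the correction took the Spearman correlation with GC from -0.27 to -0.00 at lupeol 50 against control, from -0.57 to -0.02 at lupeol 80 against control and from -0.39 to -0.02 at lupeol 80 against lupeol 50. False calls went from 1 to 1, from 4 to 1 and from 0 to 2.

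Alternatives were other size factors (RLE), no scaling factors, no expression filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a fold change of at least 2, only the 2 groups compared, and each library left out in turn. Chosen after seeing the data were the removal of each library's trend on transcript GC content and length (natural splines with 5 degrees of freedom each, as offsets, from a GC value for 97.8% of genes), the sum of control columns A and B as 1 library, and leaving out control B and lupeol 80 replicate 1 together. Similarity of libraries was described by a chi-square of counts, by correlation and by principal components of the 1000 most variable genes.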

Results

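RNA-seq measured transcript levels in THP-1 cells, a human line from an acute monocytic leukaemia, after 48 h with lupeol, a plant triterpene, or with its solvent. The 9 libraries formed 3 groups of 3: solvent control, lupeol at 50 µmol/L (lupeol 50) and lupeol at 80 µmol/L (lupeol 80). Each library held between 26134744 and 38430299 counts, and lupeol 80 replicate 1 was the deepest. Between 23472 and 26285 genes had a count in a library. The control libraries carry the names 1, A and B, because 2 of the 3 control columns shared a heading.

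Libraries of one group did not always lie nearest to each other. The chi-square per degree of freedom between 2 libraries was 5.39 for controls 1 and A and 6.54 for lupeol 50 replicates 2 and 3. Control B lay nearest to lupeol 50 replicate 1, at 8.33, while it stood at 22.7 from control 1 and 28.0 from control A. The lupeol 80 libraries stood at 49.08 (replicates 1 and 2), 65.95 (1 and 3) and 29.61 (2 and 3) from each other. Lupeol 80 replicate 2 lay nearer to lupeol 50 replicate 1, at 17.07, and to control B, at 19.71, than to its own group. No pair differed by so little that it was counted as 1 library. On principal component 1, which held 23.7% of the variance of 1000 variable genes, control B stood at 1.9 and control 1 at -18.8, with control A beside it. Component 2, with 17% of the variance, put the lupeol 80 libraries between 8.9 and 28.2 and the other 6 libraries between -14.5 and -3.1. On component 3, with 14.7%, lupeol 50 replicate 1 stood at -28.8, away from control B at -4.3.

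**Figure D1:**
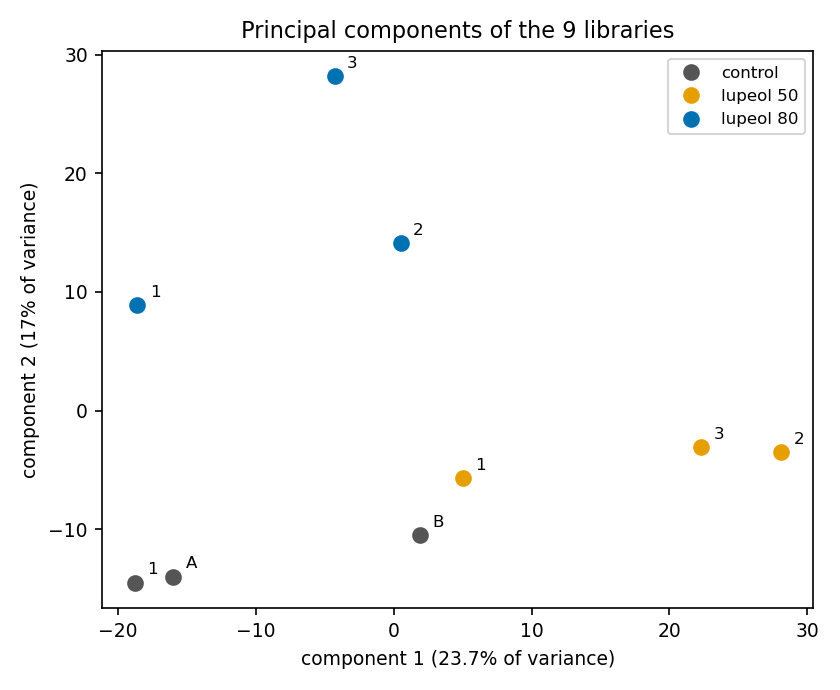
Position of the 9 libraries on principal components 1 (x axis) and 2 (y axis) of log2 CPM, 1 point per library, with the colour giving the group and the number or letter the library; doses are in µmol/L. The 3 lupeol 80 libraries lie above 8 on component 2, and control B lies beside lupeol 50 replicate 1.

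The first comparison set lupeol 50 against control and asked which transcripts the lower dose altered. Genes of cholesterol synthesis and uptake fell as a list, with all 24 tested members below control and a median log2 fold change of -0.74 (camera, adjusted p = 2.8e-10). The adjusted p = 0.59 with an estimated correlation. Genes of ER chaperones and the unfolded protein response rose, with 20 of 21 members above control and a median of 0.48 (camera, adjusted p = 8.0e-09, and adjusted p = 0.59 with an estimated correlation). Targets of ATF4, the transcription factor of the amino acid response, rose as a list, with 23 of 25 members above control and a median of 0.41 (camera, adjusted p = 1.1e-05, and adjusted p = 0.59 with an estimated correlation). NF-kB targets and inflammatory cytokines rose, with 20 of 25 members above control and a median of 0.52 (camera, adjusted p = 3.6e-04, and adjusted p = 0.59 with an estimated correlation).

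No gene of these lists passed edgeR's test over all genes, while 9 cholesterol genes were lower and 10 ER chaperone genes were higher when adjusted over the list alone. The members named here for lupeol 50 were chosen after their values were seen. DHCR7, the last enzyme of cholesterol synthesis, had 26.1 ± 9.64 CPM in control and 5.35 ± 1.85 at lupeol 50 (SD, n = 3), a log2 fold change of -2.29 ± 0.75 (SE). MVK, mevalonate kinase, stood at -1.36 ± 0.37. SREBF2, the transcription factor that drives this pathway, stood at -0.92 ± 0.29. The edgeR adjusted p of these 3 genes lay between 0.21 and 0.33. HSPA5, the main Hsp70 chaperone of the ER, had 1020 ± 203 CPM in control and 2100 ± 805 at lupeol 50 (SD, n = 3), a log2 fold change of 1.04 ± 0.32. The ER chaperone HYOU1 stood at 0.73 ± 0.22 and the co-chaperone DNAJC3 at 0.65 ± 0.15. TRIB3, a pseudokinase induced in the amino acid response, stood at 0.92 ± 0.38, with 5 ATF4 targets higher when adjusted over the list alone. IL1B, which encodes interleukin-1 beta, ranged from 16 to 89.8 CPM over the controls and from 60.8 to 173 over the lupeol 50 libraries, and 0 members of the NF-kB list were called when adjusted over the list alone.

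Antigen presentation genes fell at lupeol 50, with 16 of 19 members below control and a median of -0.33 (camera, adjusted p = 2.2e-05, and adjusted p = 0.59 with an estimated correlation). In that list 6 members were lower when adjusted over the list alone. CIITA, the coactivator of MHC class II genes, stood at -1.22 ± 0.32 and CD74, the MHC class II invariant chain, at -0.48 ± 0.15. Fatty acid synthesis genes fell by a median of 0.29 on the log2 scale in a list with 11 of 13 members below control (camera, adjusted p = 0.0012, and adjusted p = 0.59 with an estimated correlation). SCD, the desaturase of that list, stood at -1.44 ± 0.58, and 1 member was lower when adjusted over the list alone. LXR targets fell, with 8 of 10 members below control and a median of -0.48 (camera, adjusted p = 0.018, and adjusted p = 0.59 with an estimated correlation). When adjusted over the list alone, 4 LXR targets were lower and 1 was higher. Granulocyte genes fell, with 10 of 15 members below control and a median of -0.37 (camera, adjusted p = 0.016, and adjusted p = 0.59 with an estimated correlation). AZU1, a neutrophil granule protein, stood at -0.66 ± 0.15, and 4 members of its list were lower when adjusted over the list alone.

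Heat shock genes rose at lupeol 50 by a median of 0.26 in a list with 14 of 15 members above control (camera, adjusted p = 1.3e-04, and adjusted p = 0.59 with an estimated correlation). Metallothionein genes rose by a median of 0.33, with 7 of 8 members above control (camera, adjusted p = 0.018, and adjusted p = 0.59 with an estimated correlation). MYC targets of ribosome biogenesis rose by a median of 0.13, with 24 of 30 members above control (camera, adjusted p = 0.0072, and adjusted p = 0.69 with an estimated correlation). DNA replication genes fell, with 27 of 31 members below control and a median of -0.16 (camera, adjusted p = 0.0027, and adjusted p = 0.69 with an estimated correlation). When adjusted over the list alone, 1 metallothionein gene was higher, and 0 members were called in the heat shock, MYC and DNA replication lists.

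**Figure D2:**
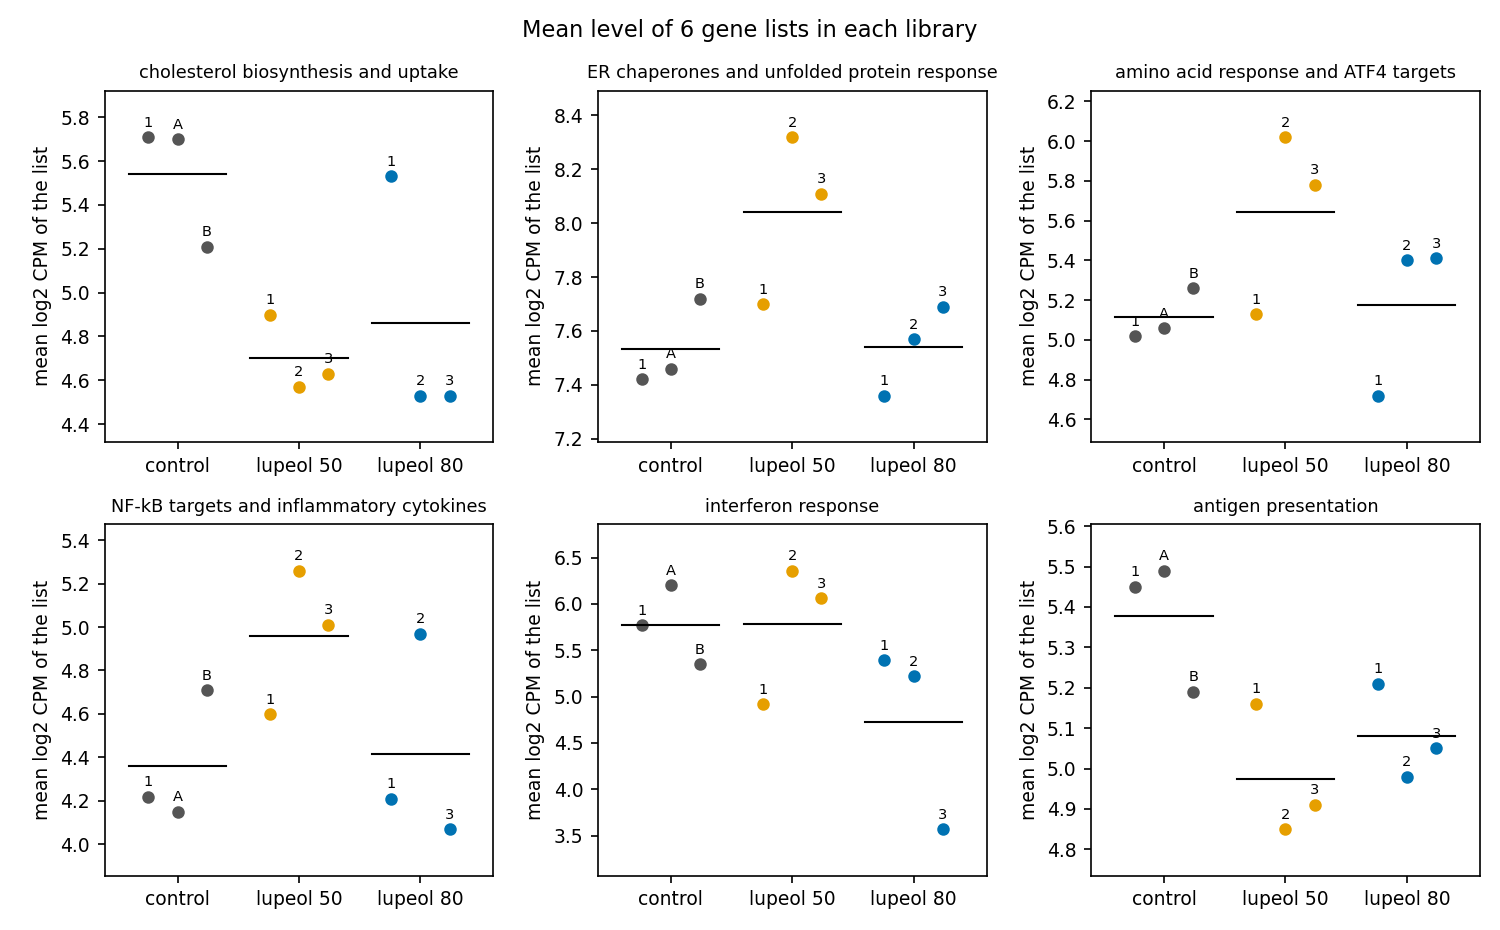
Mean log2 CPM (y axis) of the tested members of 6 gene lists in each library, by group (x axis, doses in µmol/L); each point is 1 library with its replicate name, and each line is the mean of 3 libraries. Cholesterol genes stand at 5.53 in lupeol 80 replicate 1 against 4.53 in both other lupeol 80 libraries, and interferon genes at 3.57 in lupeol 80 replicate 3 against 5.39 and 5.22.

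Lupeol 50 replicate 1 stood nearer to control B than to the other lupeol 50 libraries in several of these lists. Its mean log2 CPM was 7.70 for ER chaperones and 5.13 for ATF4 targets, against 7.72 and 5.26 in control B. Lupeol 50 replicates 2 and 3 stood at 8.32 and 8.11 for ER chaperones and at 6.02 and 5.78 for ATF4 targets. The ATF4 median was 0.69 without lupeol 50 replicate 1, 0.68 without control B, 0.67 without both control B and lupeol 80 replicate 1, and 0.27 without lupeol 50 replicate 2. Without lupeol 50 replicate 2 the NF-kB median was 0.33, and the calls of the metallothionein list (median 0.25) and the DNA replication list (median -0.05) ended. The metallothionein call also ended for genes with a mean of at least 5 CPM (median 0.24). The LXR call ended without control A (median -0.37). The granulocyte call ended without control B and without lupeol 50 replicate 3 (median -0.27 in each), and its median was -0.56 without lupeol 50 replicate 1. It also ended after each library's trend on GC content and length was removed (median -0.20) and without both control B and lupeol 80 replicate 1 (median -0.28).

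Among single genes, edgeR called 0 of 17568 at lupeol 50. At an unadjusted p under 0.05 stood 2183 genes, DESeq2 called 218, and limma-voom called 0. The 3 lupeol 50 libraries lay wholly above or below the 3 controls for 3369 genes, 19.2% of those tested. Averaged over all splits of these libraries, a gene has a 10% chance of this. Genes that move together can take a single split away from that average. The share in the other splits was not computed, so no excess over chance is read from it. The 5 genes with the smallest p had edgeR adjusted p = 0.19. They were TPST1, a tyrosylprotein sulfotransferase, at 1.55 ± 0.29, SECTM1 at -1.34 ± 0.28, the collagen gene COL9A2 at -0.91 ± 0.17, TMEM105 at -0.86 ± 0.16 and PRDX5, a peroxiredoxin, at -0.74 ± 0.15 (log2 fold change ± SE). Outside the lists described above, PLIN2, which coats lipid droplets, stood at 1.52 ± 0.55 and FOSB, an AP-1 subunit, at -1.16 ± 0.23, both chosen after their values were seen. The count was 141 without control B, 427 without lupeol 50 replicate 1, 2 without lupeol 80 replicate 1, and 913 without both control B and lupeol 80 replicate 1, a setting chosen after seeing the data. It was 520 with no expression filter and 1 with only the 2 groups compared.

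The second comparison set lupeol 80 against control. Of 17568 genes, 51 rose and 150 fell (edgeR, adjusted p under 0.05), and 41 of these 201 changed at least 2-fold. PTGS2, which encodes cyclooxygenase-2, rose from 5.26 ± 0.256 to 11.6 ± 1.69 CPM (SD, n = 3), and ANXA1, the phospholipid-binding annexin A1, from 108 ± 9.56 to 197 ± 25.7. PFDN6, a subunit of the prefoldin chaperone, fell from 55 ± 2.55 to 23.9 ± 6.05 CPM, and PSMB10, a catalytic subunit of the immunoproteasome, from 52.5 ± 6.68 to 26.1 ± 5.29. BBC3, the pro-apoptotic BH3-only protein PUMA, fell from 9.06 ± 0.755 to 4.52 ± 0.467 CPM, and CEBPA, a transcription factor of myeloid differentiation, from 316 ± 43.0 to 182 ± 21.3.

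Beside these, 9 named genes were among the largest or list-linked increases (log2 fold change ± SE). The long noncoding RNA XACT rose by 1.46 ± 0.25, CCN2, a matricellular protein, by 1.20 ± 0.23, and CLU, the chaperone clusterin, by 1.02 ± 0.20. TPD52 rose by 0.82 ± 0.14 and DSG2, a desmosomal cadherin, by 0.81 ± 0.16. The nuclear receptor NR4A2 rose by 1.21 ± 0.25, and of the immediate-early list the phosphatase DUSP1 rose by 0.73 ± 0.16 and the transcription factor KLF6 by 0.67 ± 0.15. TFRC, the transferrin receptor, rose by 0.47 ± 0.10. DOCK8-AS2 also passed the test, at 1.28 ± 0.27, but it is an antisense gene, and whether the counting used strand is not given in the sources used here, so its value is uncertain. The edgeR adjusted p of the genes named for this comparison lay between 0.012 and 0.049.

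Larger decreases were seen for PLEKHA4 at -1.24 ± 0.26, RAB24, a small GTPase, at -1.01 ± 0.24, COL9A2 at -1.01 ± 0.17 and FAM43A at -0.99 ± 0.17. RIMBP3 (-1.12 ± 0.23) and NCF1B (-1.05 ± 0.20) have near-identical copies in the genome, and ITGB2-AS1 (-1.19 ± 0.26) is antisense to ITGB2. As the treatment of reads with several alignments and of strand is not given in the sources used here, these 3 values are uncertain. Of the respiratory chain list 2 subunits fell, COX6A1 by 0.92 and NDUFA1 by 0.82 on the log2 scale. The pore-forming apoptosis protein BAK1 fell by 0.47, and PLTP, a phospholipid transfer protein, fell by 0.65.

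**Figure D3:**
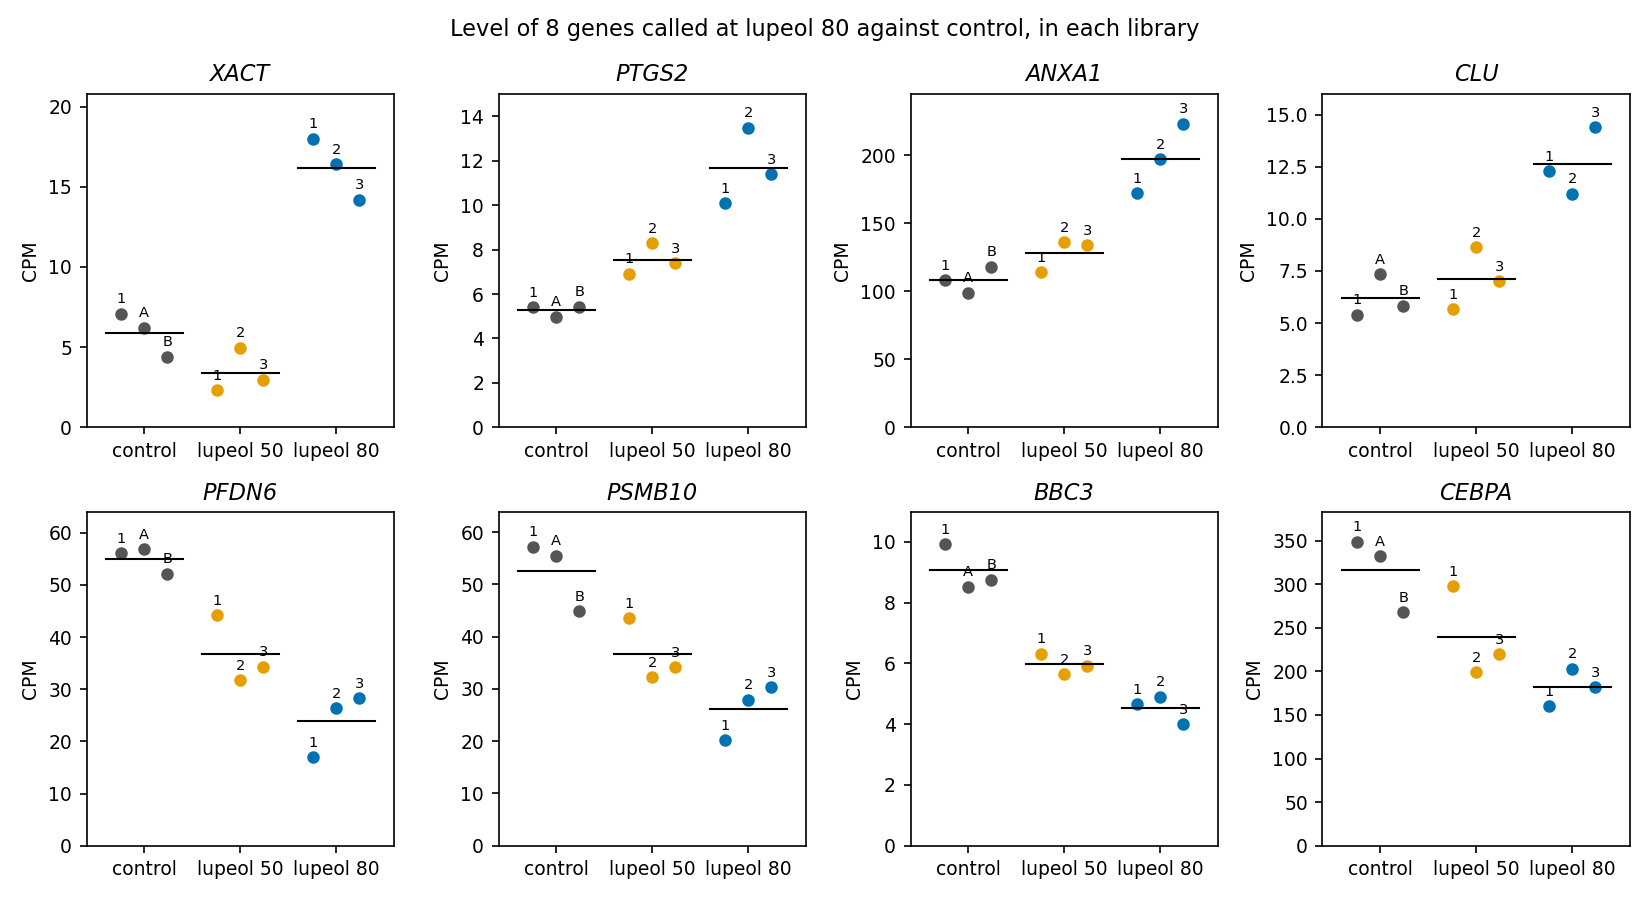
CPM (y axis, from 0) of 8 genes called at lupeol 80 against control, by group (x axis, doses in µmol/L); each point is 1 library with its replicate name, and each line is the mean of 3 libraries. For each gene the 3 lupeol 80 libraries lie wholly above or wholly below the 3 controls, as for PTGS2 at 11.6 against 5.26 CPM on average.

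Interferon response genes fell as a list at lupeol 80, with 29 of 29 members below control and a median of -0.87 (camera, adjusted p = 1.1e-06, and adjusted p = 0.68 with an estimated correlation). Of these, BST2, the antiviral protein tetherin, fell by 0.65 over all genes tested, and it was also the 1 member lower when adjusted over the list alone. Members chosen after their values were seen were IRF7 at -1.21 ± 0.53, ISG15 at -1.17 ± 0.53 and MX1 at -1.15 ± 0.77, none of which passed the test (edgeR, adjusted p from 0.28 to 0.47). MX1 had 12.8 CPM in lupeol 80 replicate 3, against 94.9 and 81.6 in the other lupeol 80 libraries. Without that replicate the median of the list was -0.57. The mean log2 CPM of the list was 5.39 in lupeol 80 replicate 1, above control B at 5.35.

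Cholesterol genes fell at lupeol 80 too, with 24 of 24 members below control and a median of -0.53 (camera, adjusted p = 3.1e-06, and adjusted p = 0.68 with an estimated correlation). FDPS, farnesyl diphosphate synthase, fell by 0.59 over all genes tested, and 3 members were lower when adjusted over the list alone. Lupeol 80 replicate 1 did not share the low level: DHCR7 stood there at 24.6 CPM, against 4.87 and 5.27 in the other lupeol 80 libraries and 26.1 ± 9.64 in control (SD, n = 3). The log2 fold changes over all 3 libraries were -1.16 ± 0.71 for DHCR7, -0.89 ± 0.36 for MVK and -0.73 ± 0.29 for SREBF2, and none passed the test. Without lupeol 80 replicate 1 the median of the list was -0.94, and without both it and control B -1.07.

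Antigen presentation genes fell at lupeol 80, with 16 of 19 members below control and a median of -0.31 (camera, adjusted p = 0.0024, and adjusted p = 0.68 with an estimated correlation). TAP1, a subunit of the peptide transporter, fell by 0.80 and PSMB9, an immunoproteasome subunit, by 0.63. Of the 19 members, 9 were lower when adjusted over the list alone. Genes of the NRF2 oxidative stress response rose, with 15 of 21 members above control and a median of 0.25 (camera, adjusted p = 0.01, and adjusted p = 0.68 with an estimated correlation). NQO1, a quinone reductase, rose by 0.65 ± 0.15, and the cystine transporter SLC7A11, chosen after its values were seen, stood at 0.97 ± 0.25 (edgeR, adjusted p = 0.091). In this list 5 members were higher when adjusted over the list alone, and its call ended without control B and without both control B and lupeol 80 replicate 1 (median 0.23 in each).

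Glycolysis and hypoxia genes fell at lupeol 80 by a median of 0.18 on the log2 scale, with 23 of 28 members below control (camera, adjusted p = 0.01, and adjusted p = 0.79 with an estimated correlation). Of the 28 members, 7 were lower when adjusted over the list alone. This call ended without control B (median -0.03) and without lupeol 80 replicate 1 (median -0.15), and control B held the highest mean log2 CPM of the list, 6.59. The call also ended after the GC and length trends were removed (median -0.08), for genes with a mean of at least 5 CPM (-0.14) and without both control B and lupeol 80 replicate 1 (0.02). Genes of mitosis fell by a median of 0.08, with 25 of 30 members below control (camera, adjusted p = 0.032, and adjusted p = 0.68 with an estimated correlation), and 1 member was lower when adjusted over the list alone. The mitosis call ended without control B (median -0.06), without lupeol 80 replicate 2 (-0.04) and without lupeol 80 replicate 3 (-0.00), and its median was -0.17 without lupeol 80 replicate 1. It also ended with no scaling factors (-0.06), for genes with a mean of at least 5 CPM (-0.07) and with control columns A and B summed (-0.08), while the list was called with a median of -0.23 after the GC and length trends were removed and of -0.15 without both control B and lupeol 80 replicate 1.

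The NF-kB list held members called in both directions at lupeol 80. The chemokine gene CXCL2 rose by 2.09 ± 0.44, from 1.79 ± 0.606 to 7.63 ± 2.53 CPM (SD, n = 3), while RELB, an NF-kB subunit, fell by 0.81. CXCL8, which encodes interleukin-8 and was chosen after its values were seen, stood at 1.90 ± 0.42 (edgeR, adjusted p = 0.086). In this list 4 members were higher and 5 lower when adjusted over the list alone, and the list as a whole was not called (camera, adjusted p = 0.64). CALR, the ER chaperone calreticulin, fell by 0.50, and it was the 1 ER chaperone gene lower when adjusted over the list alone, while that list stood at a median of -0.01.

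The count of 201 genes depended on single libraries. By edgeR it was 0 without control 1 (2251 genes at an unadjusted p under 0.05) and 1 without control A, 43 without lupeol 50 replicate 3 or without lupeol 80 replicate 3, 116 without lupeol 50 replicate 2, and 386 without lupeol 80 replicate 2. DESeq2 called 910 genes, limma-voom 174, and edgeR 3431 at an unadjusted p under 0.05. The 3 lupeol 80 libraries lay wholly above or below the controls for 4213 genes, 24% of those tested. The average over all splits is 10%, but the share in each other split was not computed, so no excess over chance is read from it. The count was 860 (385 higher, 475 lower) without both control B and lupeol 80 replicate 1, and 1 with control columns A and B summed, both chosen after seeing the data. It was 78 with only the 2 groups compared, 124 for genes with a mean of at least 5 CPM and 861 with no expression filter.

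The genes called at lupeol 80 differed in base composition. Transcripts of the genes called lower had a median GC content of 58.4%, those called higher 40.2%, and all tested genes 48.5%. Across 17173 genes the log2 fold change at lupeol 80 had a Spearman correlation of -0.50 with GC content, against -0.22 for lupeol 50 against control and -0.32 for lupeol 80 against lupeol 50. Genes are not independent replicates, so these carry no p. In lupeol 80 replicate 1 the log2 level relative to the mean of all libraries changed by -0.247 per 10 percentage points of GC, and in controls 1 and A by 0.118 and 0.130. In lupeol 80 replicates 2 and 3 it changed by -0.005 and -0.089, and in control B by 0.043. After each library's trend on GC content and length was removed, a setting chosen after seeing the data, 30 genes were called at lupeol 80, 10 higher and 20 lower. Of the 201 genes, 28 were among these 30, with PFDN6, COX6A1, PSMB10, PSMB9, ANXA1, CCN2, CLU and DUSP1 among the named ones, while BBC3, CEBPA, PTGS2, XACT and the other named genes were not called.

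**Figure D4:**
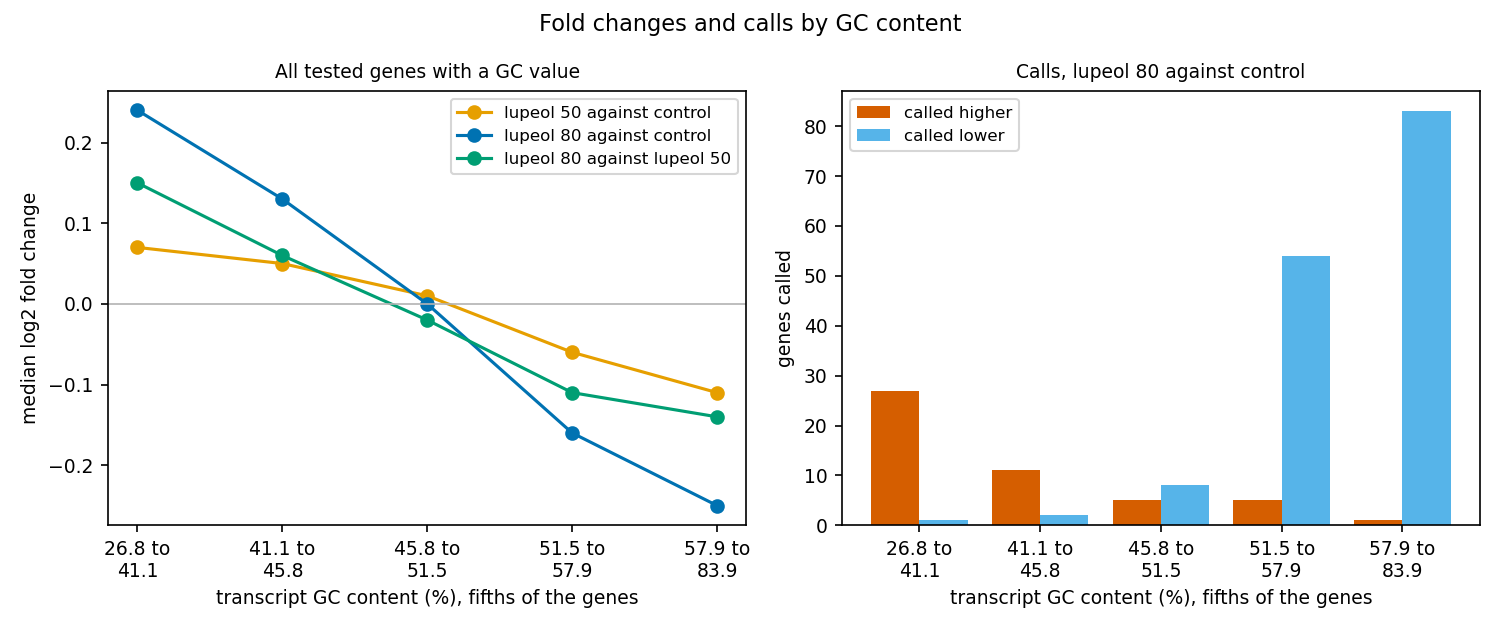
Left, median log2 fold change (y axis) of the tested genes in each of 5 bins of transcript GC content with equal numbers of genes (x axis, %), 1 line per comparison; right, number of genes called higher and lower at lupeol 80 against control in the same bins. The median at lupeol 80 runs from 0.24 in the bin of lowest GC content to -0.25 in the highest, where 83 of the genes called lower lie.

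The third comparison set lupeol 80 against lupeol 50 and tested the difference between the doses. Of 17568 genes, 6 rose and 2 fell (edgeR, adjusted p from 0.0014 to 0.036). XACT had 16.2 ± 1.89 CPM at lupeol 80 and 3.40 ± 1.37 at lupeol 50 (SD, n = 3), a rise of 2.25 ± 0.26 (log2, SE). NR4A2 rose by 1.84 ± 0.25, DUSP1 by 1.09 ± 0.16, DSG2 by 1.00 ± 0.16 and MIR23AHG, the host gene of a microRNA cluster, by 1.32 ± 0.20. MIR23AHG and ENSG00000246250, a gene without a symbol that rose by 1.92 ± 0.33, are annotated as antisense, so these 2 values are uncertain. CERCAM, a cell adhesion protein, fell by 0.76 ± 0.13 and SH3BP5L by 0.73 ± 0.11. FOSB, NQO1 and KLF6, chosen after their values were seen, stood at 1.30 ± 0.24, 0.75 ± 0.15 and 0.72 ± 0.15 and did not pass the test (edgeR, adjusted p from 0.06 to 0.065).

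ER chaperone genes were lower at lupeol 80 than at lupeol 50, with 20 of 21 members negative and a median of -0.51 (camera, adjusted p = 1.5e-07, and adjusted p = 0.83 with an estimated correlation). When adjusted over the list alone, 11 members were lower. HSPA5 stood at -0.92 ± 0.32 and HYOU1 at -1.16 ± 0.22, both chosen after their values were seen. Interferon genes fell, with 28 of 29 members negative and a median of -0.91 (camera, adjusted p = 2.3e-07, and adjusted p = 0.83 with an estimated correlation). MX1 stood at -1.10 ± 0.77, 0 members were called when adjusted over the list alone, and the median was -0.54 without lupeol 80 replicate 3. The mean log2 CPM of the interferon list was 4.92 in lupeol 50 replicate 1, below 5.39 and 5.22 in lupeol 80 replicates 1 and 2. NF-kB targets fell by a median of 0.58 on the log2 scale, with 20 of 25 members negative (camera, adjusted p = 8.7e-04, and adjusted p = 0.83 with an estimated correlation). Their median was -0.36 without lupeol 80 replicate 3, and 1 member was higher and 1 lower when adjusted over the list alone.

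ATF4 targets fell from lupeol 50 to lupeol 80, with 22 of 25 members negative and a median of -0.30 (camera, adjusted p = 8.7e-04, and adjusted p = 0.83 with an estimated correlation). When adjusted over the list alone, 3 were lower, and the call ended without lupeol 50 replicate 2 (median -0.19). The ATF4 median was -0.17 without lupeol 80 replicate 1, with or without control B, and -0.50 without lupeol 80 replicate 2 or without lupeol 80 replicate 3. Metallothionein genes fell, with 8 of 8 members negative and a median of -0.39 (camera, adjusted p = 0.0028, and adjusted p = 0.83 with an estimated correlation), and 3 were lower when adjusted over the list alone. DNA replication genes rose by a median of 0.13, with 25 of 31 members positive (camera, adjusted p = 0.0042, and adjusted p = 0.85 with an estimated correlation), and 0 were called when adjusted over the list alone. That call ended without lupeol 50 replicate 2 (median 0.06), and the median was 0.25 without lupeol 50 replicate 1 and 0.08 without lupeol 50 replicate 3. NRF2 genes rose by a median of 0.24, with 17 of 21 members positive (camera, adjusted p = 0.021, and adjusted p = 0.83 with an estimated correlation), and 1 was higher when adjusted over the list alone. The NRF2 call ended without lupeol 50 replicate 1 and without lupeol 80 replicate 3, each with a median of 0.14, and with no expression filter (median 0.24).

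Apoptosis regulators fell between the doses by a median of 0.16 on the log2 scale, with 20 of 26 members negative (camera, adjusted p = 0.036, and adjusted p = 0.83 with an estimated correlation). In this list 2 members were lower when adjusted over the list alone. The list holds both genes that promote apoptosis and genes that inhibit it, so its direction has no reading for cell death. The call ended without lupeol 50 replicate 2 (median -0.13) and without lupeol 80 replicate 2 (median -0.15), and the median was -0.09 without lupeol 80 replicate 3. It also ended for genes with a mean of at least 5 CPM (median -0.10). By fry, which tests whether members move on balance in 1 direction, this list fell from lupeol 50 to lupeol 80 (adjusted p = 0.027) and from control to lupeol 80 (adjusted p = 0.016), where its median was -0.14 and camera did not call it (adjusted p = 0.082, and adjusted p = 0.68 with an estimated correlation). It was the 1 list that fry called in each of these comparisons, and fry called 0 at lupeol 50 against control. Fry tests a list against no change, not against other genes. It was not run with a library left out or with the GC and length trends removed.

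Ribosomal protein genes fell between the doses by a median of 0.12, with 42 of 49 members negative (camera, adjusted p = 0.0032, and adjusted p = 0.87 with an estimated correlation). Lupeol 80 replicate 1 had the lowest mean log2 CPM of this list, 8.68, against 9.07 and 9.26 in the other lupeol 80 libraries. Without that replicate, with or without control B, the call ended and the median was 0.03, without lupeol 80 replicate 3 it was -0.23, and the call also ended without lupeol 50 replicate 1 (median -0.09). Heat shock genes fell by a median of 0.14, with 13 of 15 members negative (camera, adjusted p = 0.036, and adjusted p = 0.85 with an estimated correlation). Their call ended without lupeol 50 replicate 2 (median -0.12), lupeol 50 replicate 3 (-0.13), lupeol 80 replicate 1 (-0.06) or lupeol 80 replicate 2 (-0.06), and the median was -0.24 without lupeol 80 replicate 3. It also ended for genes with a mean of at least 5 CPM (-0.12) and without both control B and lupeol 80 replicate 1 (-0.06). Glycolysis genes fell by a median of 0.13, with 23 of 28 members negative (camera, adjusted p = 0.036, and adjusted p = 0.85 with an estimated correlation). That call ended without any 1 of lupeol 50 replicates 1 (median -0.12), 2 (-0.16) and 3 (-0.14), and without lupeol 80 replicate 1, with or without control B (-0.05 in each). It also ended after the GC and length trends were removed (-0.06) and for genes with a mean of at least 5 CPM (-0.11). When adjusted over the list alone, 1 glycolysis gene was lower, and 0 ribosomal protein or heat shock genes were called.

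The count of 8 genes also moved with single libraries. It was 156 without lupeol 50 replicate 1 (38 higher, 118 lower), 189 without lupeol 80 replicate 2 (68 higher, 121 lower) and 22 without control B, and it was 4 without lupeol 80 replicate 3, 3 without control A, 2 without control 1, and 1 without lupeol 50 replicate 2 or without lupeol 50 replicate 3. DESeq2 called 439 genes (186 higher, 253 lower), limma-voom 7, and edgeR 2707 at an unadjusted p under 0.05. The libraries of the doses did not overlap for 3346 genes, 19% of those tested. The average over all splits is 10%, but the share in each other split was not computed, so no excess over chance is read from it. With no scaling factors 14 genes were called, 12 higher and 2 lower, with no expression filter 659 (267 higher, 392 lower), and without both control B and lupeol 80 replicate 1 25. After the GC and length trends were removed 17 were called, 9 higher and 8 lower, and 5 of the 8 were among them; XACT, DUSP1, DSG2 and SH3BP5L were called again, and NR4A2, MIR23AHG and CERCAM were not.

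Over all 3 groups together, edgeR called 41 genes, of which 40 were also called at lupeol 80 against control. DESeq2 called 1073 and limma-voom 37. The count was 2 without control 1, without control A or without lupeol 80 replicate 3, 1 without lupeol 50 replicate 3 and 8 without lupeol 50 replicate 2. It was 242 without control B, 654 without lupeol 50 replicate 1 and 88 without lupeol 80 replicate 2. Of the 201 genes called at lupeol 80, 183 had a log2 fold change of the same sign at lupeol 50, with the smallest edgeR adjusted p = 0.19 there. These genes were selected by their difference from the same controls, which by itself favours a shared sign. No simulated value was made for genes selected in this way, so the 183 do not show a shared response. Across 17568 genes, the log2 fold changes of the doses against the shared controls had a Pearson r of 0.456 and a Spearman rho of 0.461. Unchanged groups simulated against shared controls gave a mean r of 0.503 and a mean rho of 0.462 over 20 simulations. The observed covariance was 0.101 against a simulated 0.059, a difference of 0.041. The signs were the same for 68.8% of genes, against 66.8% in the simulations. Genes were drawn independently and without GC trends in these simulations. Trends that many genes share can move such values away from the simulated ones, so these differences do not show a shared response. As 0 genes were called at lupeol 50, the shared calls were 0 and independent lists would share 0 in each direction. With 3 control libraries no split leaves 2 in each part, so part of any excess may come from the shared controls.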

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

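The test of the GC trend on the genes called lower at lupeol 80 and the comparison of library batches were chosen only after the result was seen, as was the correction for GC content and length itself.

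The test of lupeol 80 against lupeol 50 separated the doses for 8 genes, with log2 fold changes of 2.25 for XACT, 1.92 for ENSG00000246250, 1.84 for NR4A2, 1.32 for MIR23AHG, 1.09 for DUSP1, 1.00 for DSG2, -0.73 for SH3BP5L and -0.76 for CERCAM. The same test separated 11 gene lists, by camera with the preset correlation and by none with an estimated correlation. Their medians were -0.91 for interferon genes, -0.58 for NF-kB targets, -0.51 for ER chaperones, -0.39 for metallothioneins, -0.30 for ATF4 targets, -0.16 for apoptosis regulators, -0.14 for heat shock genes, -0.13 for glycolysis, -0.12 for ribosomal proteins, 0.13 for DNA replication and 0.24 for NRF2 genes.

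Cholesterol genes were lower at both doses, with lupeol 80 replicate 1 near the level of the controls. Removing each library's trend on GC content and length kept 101% of the list's median at lupeol 50 (-0.74 before and -0.74 after) and 92.6% at lupeol 80 (-0.53 and -0.49), which argues against these trends as the source. That lupeol 80 replicate 1 came from untreated cells cannot be told apart from a weaker response in it, since of 165 genes called without it 100, or 60.6%, have it on the lupeol side of the midpoint, between the bounds set before. The chi-square per degree of freedom of this library was 62.5, 71.84 and 68.03 against controls 1, A and B. It was 49.08 and 65.95 against lupeol 80 replicates 2 and 3. A source of its difference other than those named here was not tested. A lower expression of sterol genes in lupeol-treated cells stays open as a hypothesis.

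The genes called lower at lupeol 80 lie among GC-rich transcripts. Removing the GC and length trends took their median from -0.71 (SD 0.45) to -0.50 (SD 0.47), which keeps 70.1%, and 20 of 150 were called again; their median SE went from 0.14 to 0.12, so the folds shrank and the error did not grow. Fewer genes also had an unadjusted p under 0.05 (2240 against 3431), which makes the adjustment stricter, and what each part did to the calls was not separated. Without lupeol 80 replicate 1 the Spearman correlation of the fold change with GC content was -0.32, against -0.50 with it and -0.45 to -0.55 without any 1 of the other control or lupeol 80 libraries. Both values lie between the bounds set for a technical source and against one, so a trend from library preparation, or lupeol 80 replicate 1 alone, cannot be told apart from a response of GC-rich genes to lupeol. Unchanged genes simulated with these trends gave 4 calls at lupeol 80 against control. Their spread was estimated from counts that already held the trends, and they were drawn independently. This count therefore does not decide between the sources.

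Control B lies nearer to lupeol 50 replicate 1 than to the other controls. With the groups of these 2 libraries exchanged, edgeR called 1 gene at lupeol 50 against control, and with the deposited labels 0 (2183 at an unadjusted p under 0.05, DESeq2 218, limma-voom 0). By the rule set before, fewer than 10 genes after the exchange would speak against exchanged labels. The deposited labels also gave fewer than 10, a case that this rule did not cover, so the test does not separate the labelings. Exchanged labels therefore cannot be told apart from correct ones. Batches of preparation or sequencing cannot be told apart from other sources, since no label names one; the chi-square per degree of freedom of this pair was 8.33, against 22.7 and 28.0 between control B and the other controls. No biological explanation was tested, as the design names no difference within a group.

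The 6 libraries of a comparison have 10 splits into 3 and 3, too few for a share under 0.05. At lupeol 50 against control, the real split gave 0 genes and 12 lists, and the highest of the others 1 and 13, so that 3 splits gave as many lists; a real count of 0 genes leaves nothing for the splits to test. At lupeol 80 against control, the real split gave 201 genes and 6 lists, and the highest other 63 and 15, so that 1 split gave as many genes and 6 as many lists. That other split sets controls 1 and A with lupeol 80 replicate 1 against the rest. For lupeol 80 against lupeol 50, the real split gave 8 genes and 11 lists, and the highest other 2 and 11, so that 1 split gave as many genes and 2 as many lists. Over all 3 groups, 2 of 60 splits drawn from 280 gave as many genes as the real 41, the real split included; the highest other split gave 69 and the median of the others was 0. The share is under 0.05 among the splits drawn, but the draw leaves the share among all 280 uncertain, so chance is not taken as excluded.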

How the results depend on the processing

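The GC and length offsets, the sum of control columns A and B, and the joint removal of control B and lupeol 80 replicate 1 were chosen only after the results were seen. Counts below follow the order lupeol 50 against control, lupeol 80 against control, lupeol 80 against lupeol 50, and all 3 groups, with 0, 201, 8 and 41 genes as reported; where no value is given for a setting, the count was within 1.5 times that number.

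With no expression filter the counts were 520, 861, 659 and 1423; 514, 854 and 654 of the genes in the first 3 comparisons also passed the filter, and prior degrees of freedom were estimated as infinite for 91.7% of genes. DESeq2 called 218, 910, 439 and 1073. With a mean of at least 5 CPM, which tests fewer genes, the last 3 counts were 124, 5 and 1. Only the 2 groups compared gave 1 and 78 in the first 2 comparisons, from fewer libraries. No scaling factors gave 14 at lupeol 80 against lupeol 50, and RLE size factors gave 27 over all 3 groups. At lupeol 80 against control, no scaling factors gave 64 higher and 102 lower. A fold change of at least 2 left 41 at lupeol 80 against control and 5 at lupeol 80 against lupeol 50. The GC and length offsets gave 30, 17 and 13 in the last 3, the sum of control columns A and B gave 1, 20 and 19, and the joint removal gave 913, 860, 25 and 924. The causes of these differences were not tested.

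With 1 library left out, a smaller sample, counts ran from 0 to 427, 0 to 386, 1 to 189 and 1 to 654. Camera called 12, 6 and 11 lists in the first 3 comparisons, and from 11 to 13, 4 to 11 and 6 to 12 with 1 library left out. It called 12 lists at lupeol 80 against control with no expression filter, 0, 0 and 0 with an estimated correlation, and fry called 0, 1 and 1. The median of ribosomal proteins at lupeol 80 against lupeol 50 ran from -0.23 to 0.03 with 1 library left out and was 0.03 under the joint removal. The glycolysis median at lupeol 80 against control was 0.02 under the joint removal. No named gene called in its comparison changed sign in any setting run, and XACT was called at lupeol 80 against lupeol 50 in 20 of 20 settings. At lupeol 80 against control, named genes were called in from 5 settings (TAP1) to 17 (PFDN6 and PSMB10). All 36 of those calls ended without control 1, without control A, and with control columns A and B summed. The similarity of the 2 doses, as Pearson r, ran from 0.367 to 0.608 with 1 library left out and was 0.622 under the joint removal. Depth was between 26134744 and 38430299 counts per library, which limits what can be called among genes with few counts. A fold threshold was not run over all 3 groups, and a pseudocount and a second unit were not run, since the table holds counts.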

Other observations

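No test reported in this part was chosen after its result was seen.

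Lists of myeloid differentiation were not called at lupeol 80 against control by camera. The median log2 fold change was -0.15 for 26 monocyte and macrophage genes (adjusted p = 0.18), -0.27 for granulocyte genes (adjusted p = 0.066), 0.13 for 17 genes of the HOXA and MEIS1 programme (adjusted p = 0.47) and -0.43 for 13 retinoic acid targets, of which 11 were negative (adjusted p = 0.085). At lupeol 50 against control the medians were -0.07, 0.08 and -0.22 for the monocyte, HOXA and retinoic acid lists (adjusted p = 0.45, 0.29 and 0.49). For p53 targets at lupeol 80, 12 of 20 genes were negative, with a median of -0.16 (adjusted p = 0.18). Immediate-early genes at lupeol 80 had 20 of 26 members positive and a median of 0.19 (adjusted p = 0.092), and iron handling genes a median of 0.12 over 18 members (adjusted p = 0.16). Nuclear oxidative phosphorylation genes had a median of -0.14 over 35 members (adjusted p = 0.092), lysosome genes -0.05 over 26 (adjusted p = 0.59), aryl hydrocarbon receptor targets 0.08 over 7 (adjusted p = 0.64) and histone genes -0.09 over 10 (adjusted p = 0.91). PPAR targets stood at 0.18 over 14 members at lupeol 50 (adjusted p = 0.062) and at 0.02 at lupeol 80 (adjusted p = 0.85). Without a direction, fry called 0 lists at lupeol 50 against control, 13 at lupeol 80 against control and 9 at lupeol 80 against lupeol 50, which is a test of members moving either way. At lupeol 80 against control it gave adjusted p = 9.7e-06 for iron handling and 1.9e-05 for apoptosis regulators. Fry tests a list against no change, not against other genes, and edgeR gave an unadjusted p under 0.05 for 19.5% of all genes in that comparison. These calls therefore do not set the lists apart from other genes. Fry was not run with a library left out or with the GC and length trends removed.

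Few markers of other cell types passed the expression filter. B cell genes had 5 of 11 members tested and a median of -0.65 at lupeol 80 against control (camera, adjusted p = 0.16), with PAX5 the highest at 40.8 CPM. Fibroblast and endothelial genes had 7 of 14 members tested and a median of 0.03 (adjusted p = 0.91), with PECAM1 at 412 CPM. PAX5 and PECAM1 were each the only member of their list with a mean of at least 10 CPM. Whether their counts came from other cell types was not tested. T and NK cell genes (2 tested, NKG7 highest at 7.87 CPM, median -0.36), erythroid and megakaryocyte genes (3 tested, EPOR at 14.7, median -0.42) and epithelial genes (4 tested, CLDN7 at 2.18, median -0.08) were too few for a list test.

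For some lists the median, the mean and the direction of camera differ in sign. At lupeol 50 against control these are interferon genes (median 0.07, mean 0.09, test down), fibroblast genes (0.11, 0.05, down), NRF2 genes (-0.01, 0.11, up), histone genes (0.25, -0.02, up), lysosome genes (-0.04, 0.05, down) and iron handling genes (-0.03, 0.12, up). At lupeol 80 against control these are NF-kB targets (-0.14, 0.10, down), ER chaperones (-0.01, 0.02, down), DNA replication (0.04, -0.01, up), MYC targets (-0.01, 0.03, up) and fibroblast genes (0.03, -0.08, down). At lupeol 80 against lupeol 50 it is the granulocyte list (0.12, -0.10, up). Camera called none of these lists in that comparison, and fry without a direction called only NF-kB targets at lupeol 80 against control (adjusted p = 0.0012).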
